A study of Mus musculus with 12 samples.

How the data were processed

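Chromatin accessibility was measured by Omni-ATAC-seq, in which the Tn5 transposase cuts and tags open DNA in isolated nuclei, in mouse alveolar type II (AT2) cells, the surfactant-producing epithelial cells of the lung. Per the labels, 50000 cells were sorted by flow cytometry for each library from BALB/c mice aged 6 to 8 weeks, 7 days after tail vein injection of 800000 4T1 cells (a BALB/c mammary carcinoma line) or CT26 cells (a BALB/c colon carcinoma line) carrying a label. AT2 cells came from the metastatic niche or from distal lung. Each sample pooled 5 lungs, and 4 groups (4T1 distal, 4T1 niche, CT26 distal, CT26 niche) of 3 independent samples gave 12 libraries.

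The authors deposited a list of broad peaks for each library, in GRCm38 coordinates. The processing notes name MACS2 and bedtools without versions or settings, and the aligner, the filters and the annotation are not given in the sources used here. The deposited columns used were the start and end of each peak in bp, the fold enrichment of the peak over its background (a ratio within each library), and the -log10 p and -log10 q of the peak, as the authors' peak caller wrote them. No deposited peak had a -log10 q under 1, that is a q above 0.1. The lists hold no read counts, so the depth of each library is unknown, and a longer list can come from more reads or from more open chromatin. No interval or detection limit from counts was therefore computed. Peaks on the 19 autosomes and X were kept.

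Peaks of all 12 libraries were merged into regions where they overlapped by at least 1 bp. A library held a region if a peak of it overlapped the region. A region was niche-only in a model if all 3 niche libraries and no distal library held it, and distal-only in the opposite case. By chance each of these takes 5% of the regions held by exactly 3 of the 6 libraries of a model. Region counts were set against the other 9 splits of the same 6 libraries, and regions shared by both models were tested by an exact permutation of the site labels within each model (400 arrangements, smallest two-sided p = 0.01 for this count). The number of peaks was tested by a two-sided exact permutation test of the difference of means (smallest p = 0.1 within a model and 0.005 over both). The location of regions was compared with that of the other regions held by exactly 3 of the 6 libraries, by a permutation test with 100000 resamples, adjusted by Benjamini-Hochberg over 12 tests. The gene table at hand gives no strand, so a region counted as near a gene end if it lay within 1 kb of either end of a gene. No genome sequence was at hand, so the planned test of transcription factor motifs was not run.

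For each of 21631 protein-coding genes of the RefSeq annotation of GRCm38, the length under peaks was summed over the gene and 10 kb on each side (its locus). The 16823 loci with a peak in at least 3 libraries were tested. Lengths were scaled to the mean total covered length of the libraries, 500 bp was added, and log2 values were fitted with limma 3.58.1 in R 4.3.3 (4 group means, lmFit and eBayes with trend, 8 residual degrees of freedom). Log2 changes below are on this scale and depend on the added 500 bp, so no fold is given against a group whose libraries all lacked a peak in the locus. Such a group has no spread and lowers the spread that the 4 groups share, so the limma p of these loci can be too small. A locus can also pass the filter through the libraries of a single group. A locus passed at a Benjamini-Hochberg adjusted p under 0.05 over the loci tested. Neighbouring loci share regions and are not independent. In a test on simulated data, planted log2 changes of 0.5 and 1 were called in 49% and 86% of loci within 4T1 and in 71% and 91% over both models, with 0.0481% and 0.0301% of unchanged loci called. The simulated noise was normal and independent between loci. It had no floor at no peak and no difference in list length, so these rates need not hold for the real lists.

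The 25 gene lists (cell type markers and pathways) and the rule for named genes were fixed before the data were examined. The lists were tested with limma's camera at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the 25 lists. Named genes are the 10 loci with the largest rise and the 10 with the largest fall in each niche against distal comparison among those that passed with non-overlapping groups (which chance gives in 10% of loci for 3 against 3), leaving out Gm, Rik and LOC models, plus each list member that passed, and 12 genes always given. Where several loci shared the region that differed most, only the gene with the nearest end was ranked, so a locus with a larger change can be left out. Regions named are those distal-only in both models and the 10 niche-only in both models that ranked highest by the deposited -log10 p within the lists that call them. Of 357 list symbols, 325 had a tested locus; Mx1, Dnai1 and the older symbols Cyr61 and Ctgf were among those without.

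Alternatives tried were a stricter -log10 q of at least 5, the same number of peaks (42067, the length of the shortest list, taken by the deposited -log10 p) in each library, at least 50% of a region covered, fixed 1 kb bins, 3 kb around gene ends, an added 100 or 2000 bp, no scaling, loci with 2 kb or 50 kb flanks, no filter, a replicate block, and leaving out each library in turn. The same number of peaks with scaling, the gene families and the tests against loci of like coverage were added after the data were seen. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and drawn with matplotlib 3.10.9.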

Results

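Accessible regions of AT2 cells were listed for 12 libraries, 3 from each of 4 groups: AT2 cells of distal lung and of the metastatic niche, in mice carrying 4T1 or CT26 tumour cells in the lung. The study asked how chromatin of AT2 cells changes beside metastases of either tumour. The 4T1 distal libraries held 57404 ± 976 peaks (mean ± SD, n = 3), the 4T1 niche libraries 65373 ± 1597, the CT26 distal libraries 46808 ± 4206 and the CT26 niche libraries 52655 ± 2498. These peaks covered 44.2 ± 1.98, 50.9 ± 1.60, 33.2 ± 1.63 and 40.4 ± 3.69 Mb of the genome. The median peak was 673 ± 21.6, 666 ± 28.5, 623 ± 30.4 and 669 ± 29.5 bp long in the same order. The number of sequenced reads is not in the lists. The merged peaks made 83727 regions, of which 35222 (42.1%) were held by all 12 libraries.

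**Figure D1:**
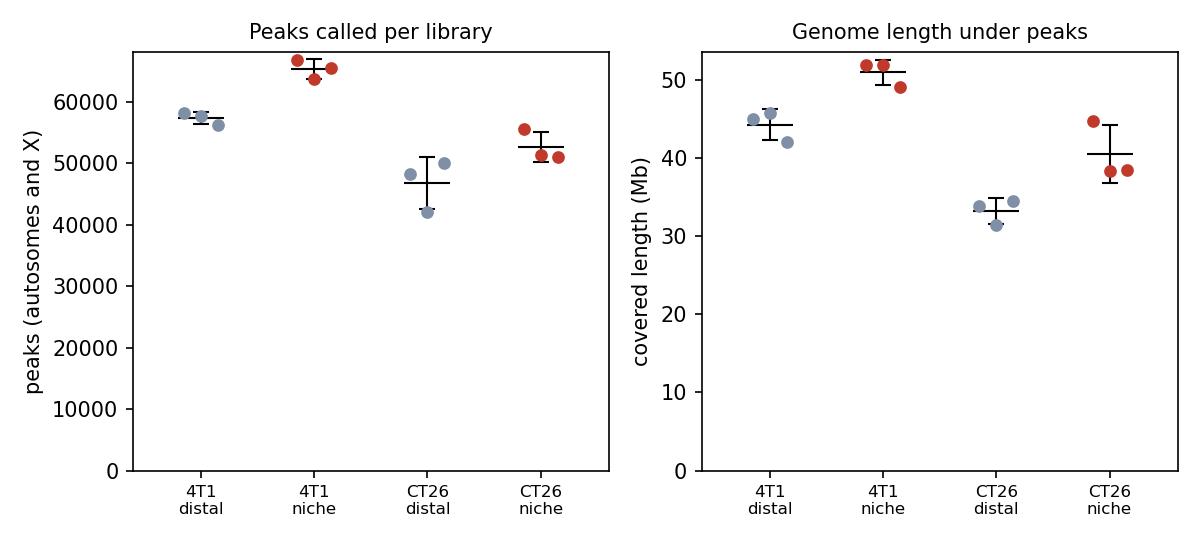
Peaks on autosomes and X (left, number) and genome length under them (right, Mb) in each library, with grey points for distal and red points for niche libraries, and the mean and SD of the 3 libraries of each group in black. Niche means lie above distal means in both models, 65373 against 57404 peaks in 4T1 and 52655 against 46808 in CT26.

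Niche AT2 cells carried more called peaks than distal AT2 cells, and the regions held by all libraries of a single site were mostly niche regions. In 4T1, 2170 regions were niche-only and 120 distal-only, and in CT26, 1303 were niche-only and 114 distal-only. In both models together, 82 regions were niche-only in each (46 with the same number of peaks in each library). None stood high in the lists. By the deposited -log10 p, their mean percentile within the lists that call them was 4.2 to 51.1, and 37.0 to 51.1 for the 10 named. A region 5713 bp from Ifih1, a cytosolic sensor of viral RNA, was among the 10 (chromosome 2, 62651969 to 62652255). Others lay close to the epidermal lipoxygenase Alox12b (chromosome 11, 69171708 to 69173125) and the vesicle fusion gene Stx16 (chromosome 2, 174067603 to 174068127). Within genes, niche-only regions of both models lay in Mpzl3 (chromosome 9, 45060165 to 45061114), Qser1 (chromosome 2, 104763127 to 104763575) and D430041D05Rik (chromosome 2, 104353972 to 104354518). The others of the 10 named had Rnf212, Gm815, Ccdc91 and Rab11fip2 as nearest gene. The regions distal-only in both models numbered 4 (20 with the same number of peaks) and lay at mean percentiles of 13.7 to 19.1. The first lay nearest to Klf3, a zinc finger transcription factor (chromosome 5, 64852688 to 64853356). Another lay within Vav2, a signalling protein of the Vav family (chromosome 2, 27323943 to 27324940). The others lay nearest to the deubiquitinase gene Usp25 (chromosome 16, 76780489 to 76781015) and 788 bp from the lipid-binding gene Sec14l3 (chromosome 11, 4079779 to 4080626). No region was niche-only in a model and distal-only in the other, and 1 to 5 were under the alternatives tried.

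Niche libraries had 13.9% more peaks than distal libraries in 4T1 and 12.5% more in CT26 (exact permutation test, two-sided, p = 0.1 in each model, the smallest possible), and 13.2% more over both models (exact permutation p = 0.005, the smallest possible). Niche-only regions were 38.8% of the 5586 regions held by exactly 3 of the 6 4T1 libraries and 27.9% of the 4663 in CT26, against 5% if all libraries held regions alike. Distal-only regions were 2.15% and 2.44%. Given the number of peaks of each library, 1588 niche-only regions were expected in 4T1 and 916 in CT26, so the counts were 1.37 and 1.42 times those expected. For distal-only regions they were 7.13 and 4.95 times those expected. The 86 regions with the same direction in both models compare with at most 9 in the other arrangements of the labels (exact permutation p = 0.01, the smallest possible). For independent lists, 20 niche-only and 0.154 distal-only regions were expected among all 62399 regions called in both models. These include the 35222 regions held by all 12 libraries, which can be of neither kind, so these expected numbers are too low. Distal-only regions lay outside genes and their ends more often than other regions held by exactly 3 libraries, in 49.2% against 37.8% in 4T1 (permutation test, adjusted p = 0.026) and 54.4% against 38.0% in CT26 (adjusted p = 0.00612). For niche-only regions this share was 41.9% in 4T1 (adjusted p = 0.0099) and 37.6% in CT26 (adjusted p = 1). The share within 1 kb of a gene end was 7.10% for niche-only regions in 4T1 (7.10% in the others). In CT26 it was 8.52% (7.79% in the others), and this share did not pass in any set. The location tests here and below draw regions as if independent, so their p do not measure the spread between libraries. Between the libraries of the 2 sites of a model, the smallest possible p is 0.1. With the same number of peaks taken from each library, the counts moved to 538 niche-only and 417 distal-only regions in 4T1 and 611 and 360 in CT26. Equal numbers of peaks also draw these counts together by construction.

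**Figure D2:**
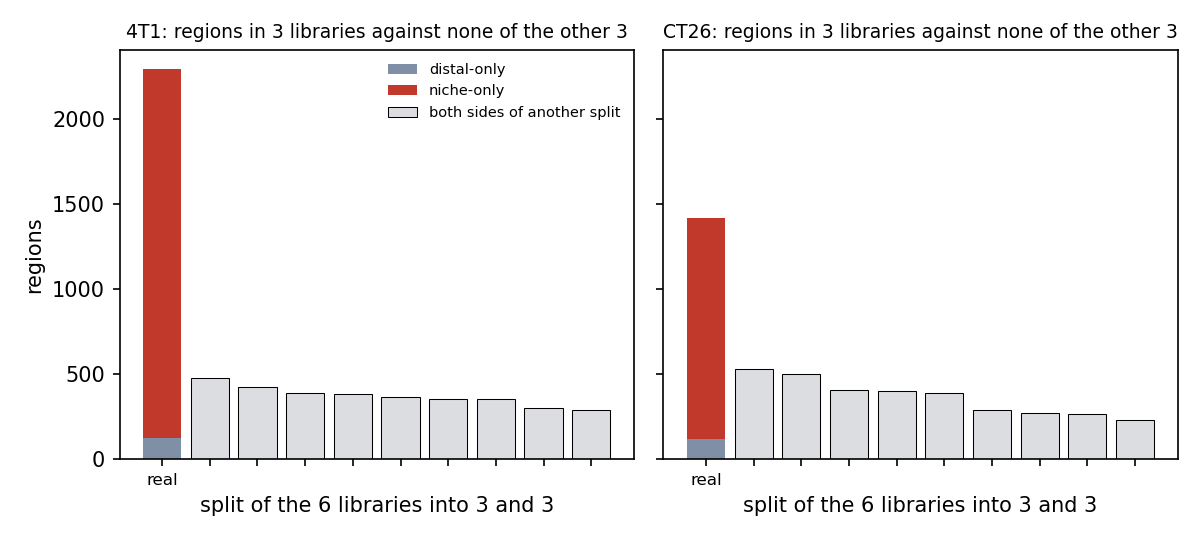
Number of regions held by 3 libraries and none of the other 3 for each split of the 6 libraries of a model (4T1 left, CT26 right). The real split (red niche-only, blue-grey distal-only) gives 2290 regions in 4T1 and 1417 in CT26, and the highest other split (light grey) 472 and 529.

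In the 4T1 model, the loci of Ccl2, Tnfaip2, Apol6 and Adamts2 gained peaks in niche AT2 cells. Ccl2, a chemokine that attracts monocytes (chromosome 11, 82035577 to 82037452), had no peak in the 4T1 distal libraries and 1.38 ± 0.31 kb under peaks in the niche libraries (SD, n = 3; limma adjusted p = 0.000521), and no peak in any CT26 library. The groups without a peak add no spread, so this p can be too small. Tnfaip2, a gene induced by tumour necrosis factor (chromosome 12, 111442450 to 111455018), rose from 0.766 ± 0.15 to 2.85 ± 0.64 kb (log2 change 1.21 ± 0.15 SE, limma adjusted p = 0.00346). Apol6, of the apolipoprotein L family (chromosome 15, 77045050 to 77057108), rose from 0.179 ± 0.17 to 2.99 ± 0.35 kb (log2 change 2.17 ± 0.24, limma adjusted p = 0.00208), and the matrix protease gene Adamts2 from 0.815 ± 0.21 to 3.91 ± 0.28 kb (log2 change 1.56 ± 0.22). The region that differed most at the Apol6 locus lay 6851 bp outside the gene, within the neighbouring gene Mb.

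Of the 25 lists, the TGF-beta and EMT list was higher in the 4T1 niche by camera (adjusted p = 0.0347). It did not pass with an estimated correlation (camera adjusted p = 0.25) or by fry (adjusted p = 0.082). A positive change was seen in 13 of its 18 loci and none passed over all loci. When adjusted over the list alone 1 passed, Twist1, a mesenchymal transcription factor. Some lists of other cell types also moved up in 4T1, and none of these passed by camera. The fibroblast and mesenchymal list had 7 of 8 loci positive (camera adjusted p = 0.0569, fry adjusted p = 0.177). The endothelial (8 of 10), neutrophil (4 of 6) and basal cell (3 of 4) lists each had a camera adjusted p of 0.235. Their fry adjusted p were 0.177, 0.0465 and 0.111. Most loci did not rise in the macrophage and monocyte (4 of 11 positive), lymphoid (4 of 10), mammary (3 of 7) and club cell (1 of 6) lists. In the NF-kB and acute inflammation list (camera adjusted p = 0.784), Ccl2 and Tnfaip2 passed over all loci and when adjusted over the list alone. Among 16823 loci, 100 were higher and 5 lower in the 4T1 niche. Further loci with the largest rises were Hrh1, a histamine receptor (1.77 ± 0.32), and Apol8 (1.66 ± 0.32). A4galt, Ecm1, Mchr1, Chst2 and Apod, which had no peak in the distal libraries, held 1.33 to 1.61 kb under peaks in the niche. The loci that fell were Olfr171 (-1.65 ± 0.26), Pdlim1 (-0.52 ± 0.10), Cd101 (-0.46 ± 0.09), Ppfia3 (-0.41 ± 0.08) and Bcl2a1b (-0.40 ± 0.07). With the same number of peaks in each library, 9 of the 69 main calls that could be tested passed, and the changes of Apol8 (-0.22) and of the TGF-beta and EMT list (mean difference from other loci -0.03) turned negative. Without each library in turn the count of 105 became 58, 58 and 47 (distal replicates 1 to 3) and 57, 26 and 39 (niche replicates 1 to 3). Without any 1 niche replicate, 96 of the 105 loci still had a peak in enough libraries to be tested.

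In the CT26 model, the loci of Iigp1, Gbp8 and 3 members of the interferon response list gained peaks in niche AT2 cells, though the list as a whole did not pass. Iigp1, an interferon-induced GTPase that acts against intracellular pathogens (chromosome 18, 60373616 to 60392634), rose from 0.502 ± 0.23 to 3.78 ± 0.78 kb under peaks (SD, n = 3; log2 change 1.99 ± 0.17 SE, limma adjusted p = 0.000298). Gbp8, a guanylate-binding protein gene, had no peak in the CT26 distal libraries and 0.845 ± 0.056 kb in the niche (limma adjusted p = 6.22e-05). The loci of Ifit2 (0.78 ± 0.13), Oas1a (0.74 ± 0.12) and Stat2 (0.65 ± 0.11), which belong to the interferon response list, also rose. The region that differed most lay within the gene for Ifit2. For Oas1a it lay 7669 bp outside the gene, and for Stat2 4833 bp outside, within Il23a. Pdpn, a surface protein of alveolar type I cells (chromosome 4, 143267409 to 143299564), rose from 1.19 ± 0.42 to 3.14 ± 0.75 kb (0.92 ± 0.16, limma adjusted p = 0.0364), and Cd44, a hyaluronan receptor, from 1.96 ± 0.26 to 3.91 ± 1.1 kb (0.59 ± 0.11).

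No list passed in CT26. The interferon response list had a camera adjusted p of 0.0618 (adjusted p = 0.276 with an estimated correlation; fry adjusted p = 0.036), with 12 of 19 loci positive, 3 higher over all loci, and 5 higher when adjusted over the list alone (Ifi44, Oas1a, Stat2, Ifit2 and Ifit3). The YAP and TEAD list and the fibroblast and mesenchymal list each had a camera adjusted p of 0.0713, with Ajuba and Tbx4 higher when adjusted over the list alone. Of 16823 loci, 88 were higher and 25 lower. Zfp652 (1.58 ± 0.23 kb), Enox1 (1.42 ± 0.36 kb), Fam78a (1.32 ± 0.30 kb), Chst2 (1.19 ± 0.64 kb), Gjb5 (1.14 ± 0.16 kb), Hoxb7 (0.995 ± 0.42 kb) and Bmp8b (0.98 ± 0.28 kb) held these lengths under peaks in the niche. They had none in CT26 distal libraries, whose lists were the shortest. In 4T1 distal libraries Zfp652 held 1.67 ± 0.38 kb and Fam78a 1.34 ± 0.89 kb, so there the CT26 distal group stood apart. Chst2 and Hoxb7 had no peak in 4T1 distal libraries either. Alox12b rose by 1.62 ± 0.32. Loci that fell included Tet2, a DNA demethylation enzyme (-0.94 ± 0.17; 2.64 ± 0.064 to 1.45 ± 0.20 kb), and Ntrk2, a neurotrophin receptor (-0.94 ± 0.13). Sorcs1 (-0.97 ± 0.14), Necab1 (-1.10 ± 0.20), Col28a1 (-0.73 ± 0.13), Pim1 (-0.60 ± 0.12), Adgrb3 (-0.57 ± 0.09) and the Wnt modulator Sfrp4 (-0.55 ± 0.11) also fell. Zfp981 and Spin2f had no peak in the niche libraries. Directions turned for Stat2 with 50 kb flanks (-0.0035), for Necab1 with -log10 q of at least 5 (0.56) and for Sfrp4 with 2 kb flanks (0.0212). With the same number of peaks in each library and scaling, 21 of the 98 main calls that could be tested passed. Enox1, Fam78a, Oas1a, Pdpn, Tet2 and Ntrk2 were among them. Iigp1 and Gbp8 were not, as none of the 18 interferon-inducible GTPase loci measured in this setting passed in CT26. Without CT26 niche replicates 1, 2 and 3 the count of 113 became 38, 41 and 61.

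Over both models, Enox1, Chst2, Iigp1 and Pdpn were among the loci higher in the niche. Enox1, a cell surface oxidase (chromosome 14, 77156248 to 77721763), rose from 0.556 ± 0.057 to 2.06 ± 0.16 kb under peaks in 4T1 and from none to 1.42 ± 0.36 kb in CT26 (SD, n = 3; limma adjusted p = 2.15e-05). Chst2, a sulfotransferase (chromosome 9, 95400926 to 95407270), went from none to 1.36 ± 0.40 and 1.19 ± 0.64 kb (limma adjusted p = 0.00074). Iigp1 rose by 1.27 ± 0.12, Pdpn by 0.65 ± 0.11 and Ifit2 by 0.59 ± 0.09. The Stat2 locus rose by 0.54 ± 0.08, most in the region within Il23a, and Plaur, the urokinase receptor, by 0.50 ± 0.09. Tnfaip2 (0.91 ± 0.10) and the endothelial adhesion gene Pecam1 (0.70 ± 0.16) also rose. Twist1, with no peak in 4T1 distal libraries, passed as well (limma adjusted p = 0.0448), and so did Ccl2 on its 4T1 libraries (limma adjusted p = 0.00298). Of the AT2 marker genes, Sftpb (surfactant protein B; chromosome 6, 72304610 to 72314373) was lower in the niche (-0.36 ± 0.07, limma adjusted p = 0.0249). Sftpb went from 4.66 ± 0.37 to 4.15 ± 0.14 kb in 4T1 and from 4.02 ± 0.14 to 3.66 ± 0.64 kb in CT26, before scaling. In CT26 that fall in length rested on niche replicate 2 (2.94 kb). Niche replicates 1 and 3 held 4.10 and 3.95 kb, within the 3.87 to 4.14 kb of the distal libraries. The change of Sftpb over both models was -0.14 without scaling (limma adjusted p = 0.172) and turned to 0.0648 with -log10 q of at least 5 (limma adjusted p = 0.797).

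**Figure D3:**
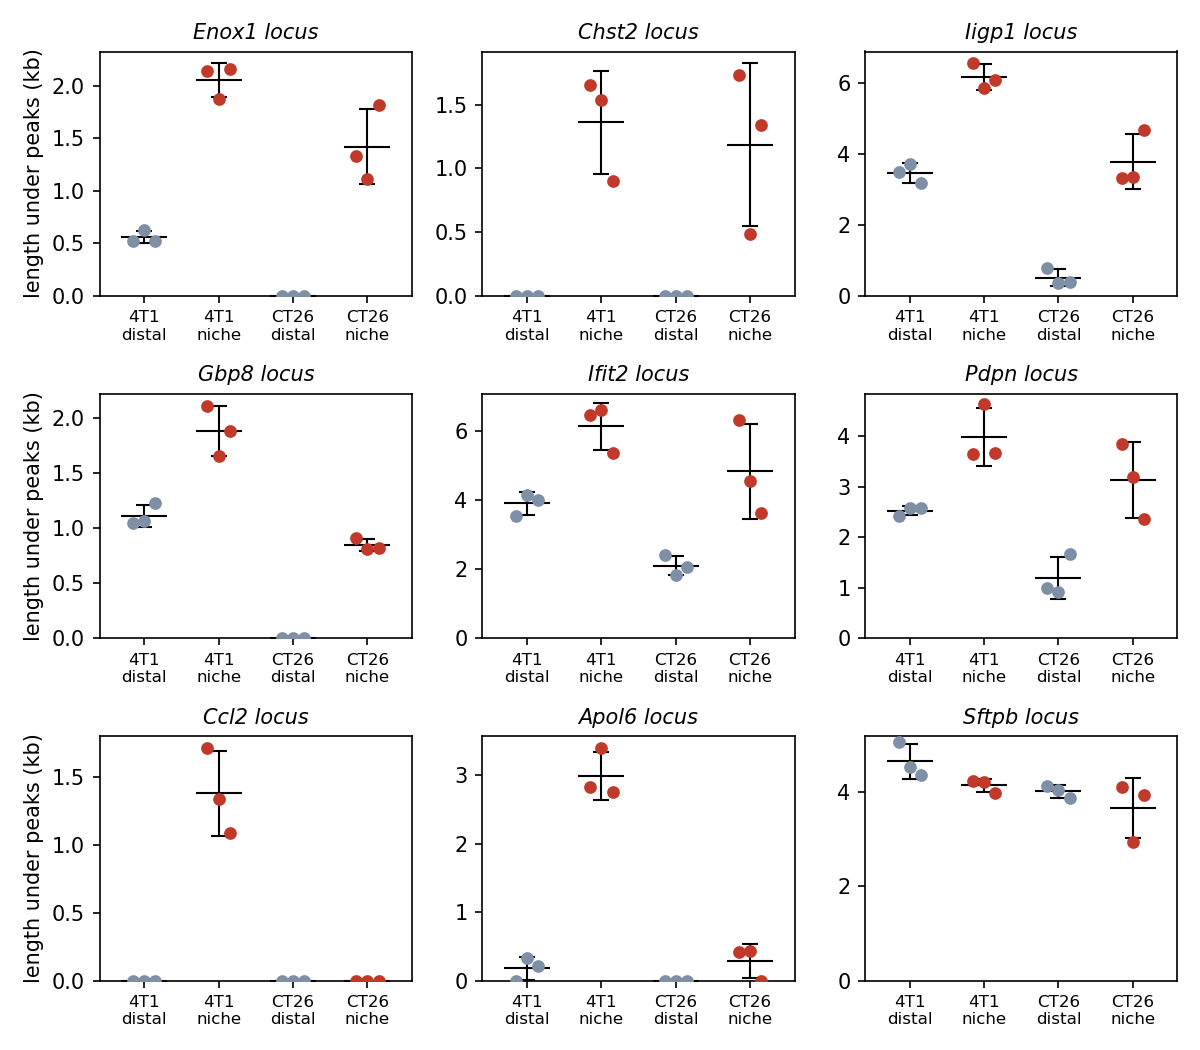
Length under peaks (kb, not scaled) in the loci of 9 genes, in each library, with the mean and SD of each group (n = 3). Ccl2 and Chst2 had no peak in the 4T1 distal libraries, and Sftpb had 3.66 to 4.66 kb in every group mean.

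Of the 25 lists, 3 were higher in the niche over both models. In the interferon response list (camera adjusted p = 0.0233; adjusted p = 0.241 with an estimated correlation; fry adjusted p = 0.0347), 12 of 19 loci were positive and Stat2 and Ifit2 passed over all loci. When adjusted over the list alone, 5 were higher (Ifi44, Oas1a, Stat2, Ifit2, Ifit3) and Irf7 lower. In the fibroblast and mesenchymal list (camera adjusted p = 0.0233; adjusted p = 0.298 with an estimated correlation), 7 of 8 loci were positive and none passed over all loci. Tbx4, a transcription factor of lung mesenchyme (0.83 ± 0.22, limma adjusted p = 0.0637), passed when adjusted over the list alone. In the YAP and TEAD list (camera adjusted p = 0.036; adjusted p = 0.298 with an estimated correlation), 9 of 13 loci were positive and none passed, either over all loci or adjusted over the list alone. None of these calls held with an estimated correlation, and none passed without scaling or with the same number of peaks in each library.

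The AT2 list did not pass (camera adjusted p = 0.938; 8 of 20 loci positive; Muc1, Sftpb, Cebpa and Sftpc lower when adjusted over the list alone), nor did the AT1 list (0.938, with Pdpn higher and Col4a3 lower over the list alone). The transitional alveolar list (0.888) held Plaur, which rose, and Mdm2, an inhibitor of p53, which fell (-0.42 ± 0.09), with Sox4 and Cdkn1a lower over the list alone. The stem and progenitor list (0.873) had Lgr6 and Cd44 higher and Sox4 and Klf5 lower over the list alone. The list of AP-1 and related factors had a camera adjusted p of 0.52 and a fry adjusted p of 0.0468, with 3 of 12 loci positive. Over the list alone, Batf3 was higher and Jun, Fosb, Junb, Maff and Fosl1 lower. Its median was -0.11 with scaling and 0.12 without. The NF-kB and acute inflammation, basal cell, macrophage and monocyte, and intestinal epithelium lists had a camera adjusted p of 0.938, as had the lipid synthesis list. The MHC class II, Wnt pathway, hypoxia and glycolysis, cell cycle, endothelial and mammary epithelium lists had 0.873, and Egln3 of the hypoxia list fell (-0.27 ± 0.06). The remaining camera adjusted p were 0.162 for TGF-beta and EMT, 0.367 for neutrophil (5 of 6 loci positive; fry adjusted p = 0.0468), 0.885 for club cell, 0.987 for ciliated cell, 0.963 for lymphoid cell and 0.546 for widely expressed control genes, of which Gapdh fell (-0.21 ± 0.04, and -0.00293 without scaling). Over their own lists alone, Flt1 and Pecam1 (endothelial), Krt17 (basal) and Cdx1 (intestinal) were higher, and Krt15 (basal) and Lck (lymphoid) lower. In the NF-kB list, Ccl2 and Tnfaip2 were higher and Icam1 and Lif lower. The median and the mean change differed in sign in the AT1, NF-kB, cell cycle, macrophage, mammary and intestinal lists.

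Of 16823 loci, 252 were higher and 149 lower over both models, a balance that depends on the processing (3956 and 25 without scaling, 254 and 492 without a filter). The other loci with the largest rises under the naming rule were Mchr1 and Hoxb7 (no peak in either distal group), Nme9 (1.17 ± 0.17) and Alox12b (1.15 ± 0.23). The gap junction gene Gja5 (limma adjusted p = 0.0155), Themis2 (0.0049) and the prostacyclin receptor gene Ptgir (0.0107) were among them too and had no peak in CT26 distal libraries. The loci with the largest falls were Duxf3 (-0.98 ± 0.20), Olfr170 (-0.97 ± 0.21), Col28a1 (-0.51 ± 0.09), Pcdh9 (-0.48 ± 0.09), Sfrp4 (-0.45 ± 0.08), Fign (-0.44 ± 0.09), Gask1b (-0.44 ± 0.10) and Mc5r (-0.40 ± 0.07). The matrix protease gene Mmp10 was lower too, with no peak in CT26 niche libraries (limma adjusted p = 0.0272). Of the genes always given, 11 did not pass: Sftpc (-0.25, limma adjusted p = 0.0686), Cdkn1a (-0.23, 0.0531), Ly6a (0.23, 0.251), Sox9 (0.54, 0.234), Krt8 (-0.05, 0.818), Nkx2-1 (-0.10, 0.337), Etv5 (-0.06, 0.764), Ager (-0.01, 0.941), Hopx (-0.24, 0.239), Lcn2 (-0.10, 0.243) and Nfkbia (-0.20, 0.189). The models shared 9 higher loci (0.523 expected for independent lists) and no lower locus (0.00743 expected). These expected numbers take every tested locus as equally likely to pass. Changes also correlated across loci (Pearson r = 0.349, Spearman correlation 0.308), which are not independent replicates.

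**Figure D4:**
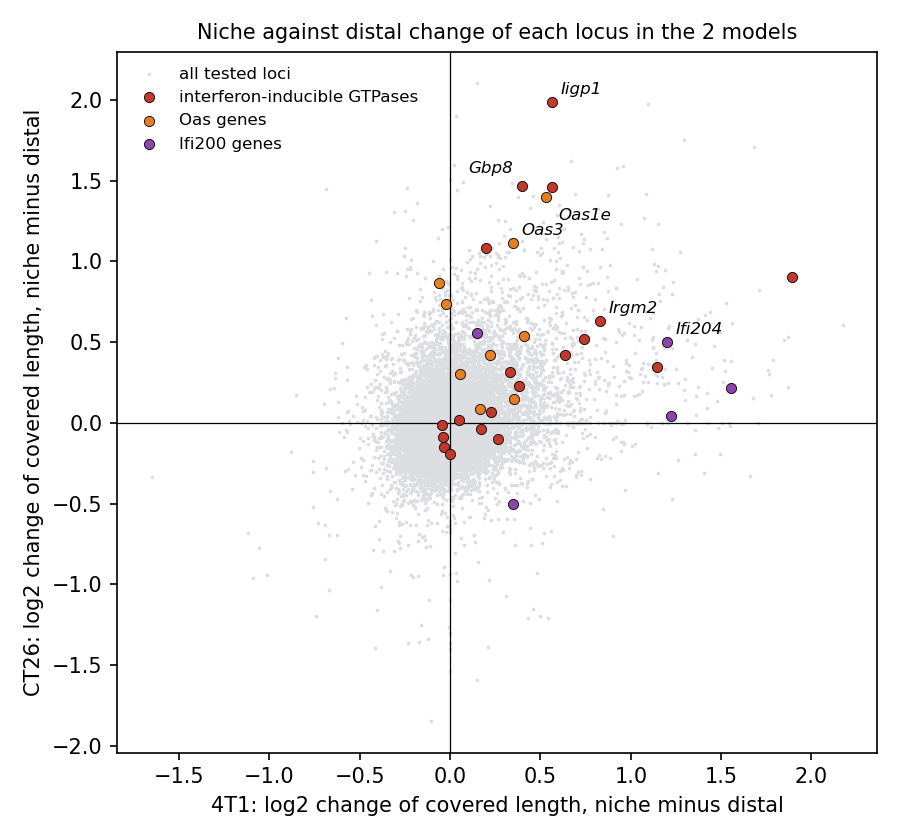
Log2 change of covered length, niche minus distal, in 4T1 (horizontal) and CT26 (vertical) for 16823 loci (grey), with loci of interferon-inducible GTPases (red), Oas genes (orange) and Ifi200 genes (purple), families chosen after their values were seen. Iigp1 lies at 0.56 in 4T1 and 1.99 in CT26.

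Scaling moved the median change of all loci by 0.19, from 0.15 without to -0.04 with it, and falls are relative to that shift. Without scaling all 252 higher loci passed and 17 of the 149 lower loci did. With the same number of peaks in each library and scaling, 27 of the 200 higher loci that could be tested passed, Enox1, Pdpn and Ptgir among them, and 8 of 146 lower loci. Leaving out 4T1 distal replicates 1, 2 and 3 gave 160, 142 and 143 loci, 4T1 niche replicates 1, 2 and 3 gave 132, 90 and 112, and CT26 distal replicate 2 and CT26 niche replicates 1 and 2 gave 248, 142 and 259.

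The niche change itself differed between the models at 10 loci, 7 lower and 3 higher in CT26 than in 4T1. Ccl2, Lsp1 (a leukocyte actin-binding protein), Apod, Nkx6-2, Mb (myoglobin), Zfp469 and 1700013G24Rik gained more in the 4T1 niche. Lsp1 held 0.454 ± 0.077 kb in 4T1 distal and 2.69 ± 0.16 kb in 4T1 niche libraries, against 0.57 ± 0.14 and 0.68 ± 0.20 kb in CT26 (SD, n = 3; limma adjusted p of the difference = 0.0223). Gbp8, Zfp652 and LOC115486128 had the larger log2 rise in the CT26 niche. Gbp8 held 1.11 ± 0.10 and 1.89 ± 0.23 kb in 4T1 and none and 0.845 ± 0.056 kb in CT26 (limma adjusted p = 0.0223). Its rise in kb was similar in the models before scaling, so its log2 difference depends on the lack of peaks in CT26 distal libraries. No gene list differed between the models; the lowest camera adjusted p was 0.0596, for the basal cell list (adjusted p = 0.647 with an estimated correlation), and 1482 loci had an unadjusted p under 0.05. With the same number of peaks in each library none of the 7 of these loci that could be tested passed, and 5 of 100 splits of the libraries gave 10 loci or more. Without 4T1 distal replicate 3, any 4T1 niche replicate or CT26 niche replicate 2, no locus passed (limma).

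AT2 cells of distal lung also differed between the models, which compares AT2 cells away from either tumour. Single loci of immune genes moved both ways, with Lck, a T cell kinase (0.41, limma adjusted p = 0.0399), higher in CT26 than in 4T1 distal libraries and others lower. The lower ones included Cd3e, a T cell receptor subunit (1.74 ± 0.58 kb in 4T1 and none in CT26; SD, n = 3; limma adjusted p = 0.0108), Itgam, an integrin of myeloid cells (-1.70, limma adjusted p = 0.0399), the MHC class II gene H2-Oa (-1.68, 0.0399) and Iigp1 (-1.77, 0.00121). Zinc finger genes Zfp600 (2.39; 0.143 ± 0.25 to 2.22 ± 0.83 kb, limma adjusted p = 0.0209) and Zfp992 and Zfp981 (no peak in 4T1 distal libraries) were higher in CT26. These genes were chosen after their values were seen. No list passed; the lowest camera adjusted p was 0.119, for the MHC class II and the YAP and TEAD lists.

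Of 16823 loci, 569 were higher and 276 lower in CT26 than in 4T1 distal libraries, and without scaling 20 and 4853. The labels give no library batch, so the tumour model and a difference in library preparation cannot be told apart. Without 4T1 distal replicates 1, 2 and 3 the count of 845 became 28, 26 and 34 (6, 5 and 7 higher). Without CT26 distal replicates 1, 2 and 3 it became 153, 93 and 235 (38, 28 and 89 higher). Most of the loci called were then lower, as with the same number of peaks and scaling (28 higher, 36 lower). With -log10 q of at least 5 most were higher (4213, and 877 lower), so the balance depends on the processing and on single libraries.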

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

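Every test of an explanation in this part was chosen after the result it concerns was seen.

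The change between niche and distal AT2 cells differed between the models at 10 loci (limma interaction, adjusted p = 0.0223 to 0.0436). The change in CT26 minus that in 4T1, in log2 of covered length plus 500 bp, was -1.70 for Ccl2, -1.57 for Lsp1, -1.52 for Apod, -1.31 for Nkx6-2, -1.13 for Mb, -1.003 for 1700013G24Rik and -0.91 for Zfp469, loci that gained more in the 4T1 niche. It was 0.76 for LOC115486128, 1.07 for Gbp8 and 1.96 for Zfp652, loci with the larger log2 rise in the CT26 niche. Ccl2, Apod and Nkx6-2 had no peak in 4T1 distal libraries and Gbp8 and Zfp652 none in CT26 distal libraries, so these sizes depend on the added length. The direction turned for Gbp8, Zfp469 and Zfp652 with -log10 q of at least 5 and for 1700013G24Rik at equal numbers of peaks. Of 100 splits of the libraries within the models, 5 gave as many loci and the highest other gave 48 against the real 10, so chance cannot be excluded. A split with several times the real count points to a structure of the samples, which was not tested further and can be the site effect itself where a split keeps part of it.

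The lists also hold 43 peaks on chromosome Y, 2 to 6 per library, which no comparison used; the labels do not give the sex of the mice.

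The larger number of niche-only than distal-only regions was weighed against the longer niche lists. At equal numbers of peaks per library the ratio of niche-only to distal-only regions was 1.29 in 4T1 and 1.70 in CT26, but equal numbers push these counts together, so the part of the excess that may come from list length (and so from depth) cannot be told apart from a gain of open regions. The sites separated in more regions than expected from the number of peaks of each library. Observed over expected separating regions was 1.43 in 4T1 (other splits at most 1.04) and 1.51 in CT26 (at most 1.16) for all peaks, and 3.05 (at most 0.911) and 2.65 (at most 0.953) for equal numbers. All splits of a model share the regions held by exactly 3 libraries, so a high real split lowers the others by construction. The splits of a model are also too few for a share under 0.05, and equal numbers of peaks do not equalise depth. Niche biology, depth and sample preparation all stay open.

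The separating regions numbered 2290 in 4T1 against 472 in the highest other split, and 1417 against 529 in CT26; 1 of 10 splits, the real one, gave as many in each. For loci, 4T1 gave 105 against 0, CT26 113 against 5 and the distal comparison 845 against 2, again in 1 of 10 splits, and for gene lists in 4T1, 4 of 10 splits gave as many as the real 1 (highest other 1). In all of these the splits are too few for a share under 0.05. Over both models, 1 of 100 splits, the real one, gave as many loci as the real 401 (highest other 33). This share of 0.01 speaks against chance for this count if the libraries are unpaired. Pairing cannot be excluded in 4T1, and with a replicate block 81 loci passed. For gene lists, 2 of 100 splits gave as many as the real 3; the highest other split also gave 3, and all 3 calls were lost with an estimated correlation (adjusted p = 0.241, 0.298 and 0.298).

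The 149 loci lower in the niche over both models, Sftpb, Mdm2 and Gapdh among them, were weighed against the scaling to total covered length. Their median change was -0.24 with scaling and -0.039 without, but the median of all loci moved by 0.19 as well, so this does not tell a fall of these loci from a rise of the others. With -log10 q of at least 5 their median was -0.22 (129 of 140 negative) and with the same number of peaks and scaling -0.16 (145 of 146 negative), where 5 and 8 passed. They lie below other loci in these settings, and whether they lost open chromatin or may owe their fall to the scaling stays open.

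The fibroblast and mesenchymal list, higher in the niche over both models by camera (adjusted p = 0.0233; 0.298 with an estimated correlation, and none of 8 loci past the threshold), was weighed against the make-up of the sorted cells. A smaller share of AT2 cells would raise every other cell type alike. The list rose above the macrophage and lymphoid lists by 0.401 (exact permutation p = 0.005, the smallest possible) and above these with the neutrophil (0.137) and endothelial (0.102) lists by 0.335 (p = 0.01), but at equal numbers of peaks by 0.229 (p = 0.025) and 0.161 (p = 0.165), which leaves this open. More weak peaks in the niche may also account for it, since the list was 0.338 above random loci of like coverage (permutation p = 0.0003) but fell to -0.0145 with -log10 q of at least 5. Fibroblasts that passed the cell sort stay open too (0.155 at equal numbers of peaks, exact permutation p = 0.135; Col1a1 at -0.00259 and Twist2 at 0.01), as does a change within AT2 cells, which was not tested.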

How the results depend on the processing

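The same number of peaks in each library together with scaling was chosen after the data were seen, as was every test of a gene family; the other alternatives were planned. The niche comparisons gave 86 passing results for named loci. A locus counts once in each comparison where it was named, and members of the families chosen after their values were seen are included. Of these results, the direction held in 86 of 86 without a filter (61 passed), without scaling (74) and with 100 or 2000 bp added (71 and 82). It also held in 86 of 86 with a replicate block (38 passed) and without each library in turn (36). The filter and the block leave the size of each change as it was, so no direction could turn there. Loci named for non-overlapping groups within a model could not turn either with another added length or without a single library. With 2 kb flanks 74 of 75 that could be tested held it (45 passed), with 50 kb flanks 85 of 86 (57), with -log10 q of at least 5, 53 of 57 (12), with the same number of peaks 63 of 65 (19), and with that number and scaling 64 of 65 (13). Where no cause is named below, the cause was not tested.

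The excess of peaks in niche libraries was 14.8% with -log10 q of at least 5 (exact permutation p = 0.015), 18.5% for covered length (p = 0.005) and 10.5% to 15.2% without each library. With -log10 q of at least 5, 4T1 niche-only regions numbered 1004 and CT26 distal-only regions 40, and the share of CT26 niche-only regions near a gene end was -2.96 points from the others (unadjusted permutation p = 0.022), turned from 0.725. At equal numbers of peaks, niche-only and distal-only regions numbered 538 and 417 in 4T1 and 611 and 360 in CT26, and 4T1 distal-only regions near a gene end were at -3.71 points (unadjusted permutation p = 0.017), turned from 0.40. At 50% of a region covered, 4T1 distal-only regions numbered 194. Regions niche-only and distal-only in both models numbered 46 and 20 at equal numbers of peaks, 30 and 2 with -log10 q of at least 5, 71 and 0 at 50% covered and 130 and 5 in 1 kb bins; without a library niche-only ones numbered 85 to 168 (140, 165 and 168 without 4T1 distal replicate 1 and CT26 niche replicates 2 and 3) and distal-only ones 4 to 9 (7 and 9 without 4T1 niche replicates 1 and 2, 8 without CT26 distal replicate 2). In fixed 1 kb bins the counts were 3591 and 267 in 4T1 and 2673 and 197 in CT26. Within 3 kb of a gene end, CT26 niche-only regions were at 2.56 points (unadjusted permutation p = 0.034).

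The number of changed loci in 4T1, CT26, both, the difference and the distal comparison was 105, 113, 401, 10 and 845. Without scaling it was 569, 2027, 3981 (3956 higher, 25 lower), 25 and 4873, since longer lists then raise most loci. With -log10 q of at least 5 it was 44, 224, 192, 81 and 5090, and with a replicate block 31, 8, 81, 1 and 9, which takes degrees of freedom. Under equal numbers of peaks it was 624 in CT26, 942 in both and 28 in the difference, and with scaling added 45 in 4T1, 82 in both and 64 in the distal comparison. With 50 kb flanks it was 171 in 4T1, 309 in CT26 and 721 in both, and with 2 kb flanks 17 in the difference and 1802 in the distal comparison. Without a filter it was 61 in CT26, 746 in both (254 higher, 492 lower), 39 in the difference and 1537 in the distal comparison, and with 100 bp added 62 in 4T1.

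Gene lists that passed in 4T1 numbered 0 with 2 kb or 50 kb flanks, with -log10 q of at least 5 and with the same number of peaks, scaled or not, and 2 with a replicate block. In CT26 they numbered 2 with 2 kb flanks, 1 without a filter and 1 with the same number of peaks and scaling. Over both models they numbered 1 with 2 kb flanks and 0 without scaling, with -log10 q of at least 5 and with the same number of peaks, scaled or not.

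Besides the location results above, directions turned as follows, none of them past the threshold after the turn. With -log10 q of at least 5: Egln3 (0.0186), Pcdh9 (0.0177), Sftpb (0.0648) and the fibroblast and mesenchymal list (-0.0145) over both models, Necab1 in CT26 (0.56), and Gbp8 (-0.21), Zfp469 (0.16) and Zfp652 (-0.46) in the difference. At the same number of peaks: Apol8 (-0.22), Cd101 (0.00469) and the TGF-beta and EMT list (-0.0323) in 4T1, and 1700013G24Rik in the difference (0.0672). After scaling was added: Apol8 (-0.21), the TGF-beta and EMT list (-0.0275), 1700013G24Rik (0.00505) and the keratin family over both models (-0.0355). With 2 kb flanks Sfrp4 in CT26 was at 0.0212, and with 50 kb flanks Stat2 in CT26 at -0.0035.

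Leaving out each library, which lowers the sample number, gave 26 to 58 loci in 4T1 and 38 to 114 in CT26 (38, 41 and 61 without niche replicates 1 to 3). Over both models it gave 90 (without 4T1 niche replicate 2) to 359 loci. The difference gave 0 without 4T1 distal replicate 3, CT26 niche replicate 2 or any 4T1 niche replicate (limma), 1 or 2 without 4T1 distal replicates 2 and 1 or CT26 niche replicate 3, and 18 without CT26 distal replicate 3. The distal comparison gave 26 to 235. Regions of a single site rise when a library is left out, since fewer must share them: 4T1 niche-only to 2727 to 3443 and distal-only to 235 to 353, CT26 niche-only to 1631 to 2448 and distal-only to 182 to 511. Moves over 1.5 times came without 4T1 niche replicates 1 and 2 (3342 and 3443 niche-only), CT26 distal replicates 1 and 3 and niche replicates 2 and 3 (2131, 2448, 2340 and 2368 niche-only), and each library for distal-only regions. The share near a gene end was 0.164 to 1.66 points for CT26 niche-only and -4.29 to -0.459 for distal-only regions, with an unadjusted permutation p under 0.05 without CT26 distal replicate 2 (1.66 and -3.77) and niche replicate 2 (-4.29). Lists numbered 0 to 2 in 4T1 (2 without distal replicate 1, 0 without distal replicate 2 or niche replicates 1 and 3) and 0 to 2 in CT26 (1 without distal replicate 3, 2 without niche replicates 2 and 3). Over both models they numbered 1 to 3 (1 without CT26 distal replicate 1 or niche replicate 1).

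Libraries with the same replicate number correlated at 0.0892, 0.0374 and 0.0285 in 4T1 and at 0.0113, 0.0175 and -0.0441 in CT26 after the group means were removed. Those with different numbers correlated at -0.0596 to 0.0246 in 4T1 and at -0.0932 to 0.0921 in CT26. The same-number values in 4T1 all lay above the 4T1 range, so pairing cannot be excluded there. The main fit did not pair samples. With a replicate block, 31 loci passed in 4T1, 8 in CT26 and 81 over both models. Depth is not given, so its share in these counts was not estimated.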

Other observations

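Each family in this part, and each test on it, was chosen after the changes of its members were seen.

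Loci of interferon-inducible GTPases, enzymes that act against intracellular pathogens, were higher in the niche over both models. Of 19 such loci measured, 15 had a positive change and 6 passed: Iigp1 and Irgm2 (0.73 ± 0.13 SE, limma adjusted p = 0.021), Tgtp2 (0.75, 0.00728), and Gbp8, F830016B08Rik and Gm4951. Gbp2 (0.07), Gbp3 (-0.09), Gbp5 (-0.06) and Irgm1 (-0.03) did not pass; without scaling, which takes the median of all loci to 0.15, Gbp3 was at 0.11, Gbp5 at 0.15 and Irgm1 at 0.19. All 9 loci of the Oas family, which make the activator of an RNA-degrading enzyme, were positive, with Oas1e and Oas3 past the threshold. Of 5 Ifi200 loci, sensors of DNA, 4 were positive and Ifi203 (0.89) and Ifi204 passed.

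A hypothesis is that niche AT2 cells, or cells sorted with them, may open interferon-induced loci beyond what longer lists give. It was tested with the same number of peaks in each library and scaling. The GTPase family then differed from other loci by 0.352 (camera adjusted p = 0.0381 with an estimated correlation), the Oas family by 0.536 (0.00338) and the Ifi200 family by 0.629 (0.00338). These families were chosen for their rise in the same libraries, so such p restate the choice and do not bear the hypothesis out. The interferon response list, fixed beforehand, was at 0.148 in this setting and did not pass (camera adjusted p = 0.0516), which leaves the hypothesis open. Against random loci of like coverage the rises were 0.464 and 0.40 (permutation p = 1e-04 each, the smallest possible) and 0.327 (p = 0.02). Members lie in clusters and share regions, so these p are too small, and without scaling the estimated-correlation p was 0.00213, 0.221 and 0.319.

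Apol and Hox loci were also tested for a rise beyond what longer lists give, and no list fixed beforehand holds either family. All 8 Apol loci were positive (Apol6 and Apol9b passed; camera adjusted p = 0.0133 with an estimated correlation), but with the same number of peaks and scaling 3 could be measured, at 0.278 (adjusted p = 0.657). Of 32 Hox loci 22 were positive, with Hoxa2, Hoxb7 and Hoxb8 among those that passed (adjusted p = 0.0815 with an estimated correlation); with the same number of peaks and scaling they were at 0.0352 (adjusted p = 0.962). With an estimated correlation, Ccl chemokines and collagens (adjusted p = 0.0529 each), keratins (0.139), integrins (0.153) and claudins (0.981) did not pass.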
